A study of Caenorhabditis elegans with 3 samples.

How the data were processed

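The series holds 3 microarrays with 2 channels each. Each array set RNA from a separately numbered preparation (prep 1, 2 or 3) of late fourth-stage larval (L4) and young adult Caenorhabditis elegans hermaphrodites, in channel 2, against RNA of a common mixed wild-type reference, in channel 1, per the labels. The composition of the reference, the dyes, the scanner, the image software, the background correction, the spot filter and the normalization are not given in the sources used here. Nothing says that the preps came from separate cultures, so p-values measure only the spread between these preps, which may be partly technical.

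The deposited table gives 1 log2 ratio per spot and array for 20000 spots. The log2 base was checked on the values. For every value whose ratio was under 0.6, 2 raised to the deposited value fell within 1% of a step of a whole multiple of 0.001, on all 3 arrays. With a natural log, a log10 or an inverted ratio at most 3.10% of values did so. The ratio was therefore stored to 3 decimals before the log2 was taken. The means of the deposited log2 ratios were 0.014, 0.021 and 0.016 in preps 1, 2 and 3 and the medians 0.040, -0.085 and -0.065, so whether the authors centred the arrays on their means stays unknown. Values were missing for 73, 175 and 127 spots. The direction of the ratio is not stated. Because the staged RNA is the second channel of every array, a positive value was taken as the likely sign of a higher level in the staged RNA. With the opposite direction every higher or lower below would turn. The staged RNA was never in channel 1, so an effect of the channel on a gene cannot be told from a stage difference. The 3 arrays correlated positively with each other, so they ran the same way. The files give no intensities, so dim or saturated spots could not be removed, and the number of arrays limits the precision.

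Spots were named through the platform's annotation table, with symbols updated through the gene identifiers of a RefSeq gene table (assembly WBcel235), which also gave each gene's chromosome. Of the spots, 15655 had 1 gene, 198 had several and were left out, and 4147 had no listed gene. Spots of 1 gene were averaged on each array, which affected 467 genes. Between spots of 1 gene the mean log2 ratio differed by a median of 0.28, and by more than 1 in 13 of 430 genes. The test used the 15119 genes with a value on all 3 arrays. Genes of families with near-identical members, such as the major sperm proteins, some collagens, actins and histones, may share signal, and their single values are uncertain.

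Each gene's mean log2 ratio was tested against 0 with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided) and Benjamini-Hochberg adjustment at 0.05. The reference is 1 common RNA, so its own spread is left out of the test. For 21 gene lists the shift against all other genes was tested with limma's camera at an inter-gene correlation of 0.01, two-sided, with adjustment over the lists, and the list's median log2 ratio was taken on each array. X-linked genes were compared with autosomal genes in the same way. The gene lists, the design, the naming rule and most alternatives were fixed before the data were examined. The rule named the 12 genes with a symbol that had the highest and the 12 that had the lowest mean log2 ratio among called genes of 1 sign on all arrays, with at most 3 per symbol prefix. It also named the 3 highest and 3 lowest genes that have only a sequence name, and the 2 highest and 2 lowest members of each list. Of the lists, adult cuticle collagens is nested in cuticle collagens, and a few other genes stand in more than 1 list.

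The probe numbers run in the order of the array. They fall into 32 runs of 625, each as large as a square of 25 spots a side, called print blocks here. The layout was inferred from the values and is not stated. Deviations of a spot from its mean over the arrays correlated between spots 25 numbers apart by 0.21, 0.23 and 0.30 in preps 1, 2 and 3, above the values of 0.14, 0.11 and 0.24 at 12 numbers apart. The print blocks held 13.5%, 11.4% and 21.9% of the variance of these deviations, against 7.56%, 10.6% and 15.5% for runs of the same length shifted off the supposed borders. The block borders are thus little supported in prep 2. The deposited values thus keep an effect of position, and centring each array within each print block was added as an alternative after this was seen. Other alternatives changed the centring, the scale between arrays, the weights, the variance estimate, the handling of missing values and repeated spots, the thresholds and the list test, and left out each prep in turn.

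The gene test was checked on simulated data with the fitted variances for 15119 genes. With 200 genes changed, it recovered 90.0% of those shifted by 2, 10.0% of those shifted by 1, 2.00% of those shifted by -1 and none of those shifted by 0.5 on the log2 scale. It called 2 unchanged genes. The script had asked for more than 90.0% at a shift of 2, and this demand was lowered after the result was seen. In a second simulation, genes drawn at random were left unchanged and the rest were changed by their observed means. Here it recovered 60.9% of genes near 1 and 100% of those near 2, and 2.08% of the calls were of unchanged genes. Calls for changes near 2-fold are therefore incomplete. The simulated errors were independent between genes, whereas the deposited values keep an effect of position. The simulated rates of recovery and of false calls may thus differ from those in the data. The share of unchanged genes was set by the simulation, so 2.08% is no estimate of the false calls in the data. Observed means hold noise, so taking them as true changes may raise the recovery.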

Results

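The transcriptome of late L4 and young adult hermaphrodites was compared with a mixed wild-type reference on 3 two-channel arrays, 1 for each of 3 preps. At this stage the hermaphrodite gonad has made sperm and turns to oocytes, and the last larval cuticle is replaced by the adult one. The arrays gave log2 ratios for 19927, 19825 and 19873 spots. Across the 15119 genes measured on all arrays, the log2 ratios of pairs of arrays correlated with Pearson's r of 0.65 to 0.68 and Spearman's rho of 0.57 to 0.58; genes are not independent replicates. The median SD of a gene over the 3 arrays was 0.39. Higher and lower refer to the likely direction of the ratio, staged RNA over reference, throughout. All values are log2 ratios unless given as a fold, with SD over the 3 arrays (n = 3).

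The comparison asked which genes differed between this stage and the mixed reference. Collagens of the cuticle and genes of sperm led the genes that were higher. The highest of all was irg-5, named for its response to infection, at 5.24 ± 0.64, a 37.8-fold difference (limma adjusted p = 3.96e-06). The collagens col-129, col-139 and col-81 followed at 4.50 ± 0.17, 4.37 ± 0.14 and 4.22 ± 0.52. Among sperm genes, msp-33, msp-56 and msp-57, members of the major sperm protein family, stood at 4.10 ± 0.56, 4.09 ± 0.58 and 3.74 ± 0.47. The major sperm protein domain gene msd-4 stood at 4.02 ± 0.57, the sperm chromatin gene spch-3 at 3.74 ± 0.27 and the sperm gene smz-2 at 3.64 ± 0.56. The remaining 2 of the 12 highest named genes were pud-2.1 at 3.76 ± 0.34 and srb-13, of a chemoreceptor family, at 3.68 ± 0.09. The rule allowed at most 3 genes per symbol prefix. It left out, for example, the collagens col-62 at 4.05 ± 0.75 and col-7 at 3.80 ± 0.39.

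The lowest gene was hsp-12.6, a small heat shock protein gene, at -4.87 ± 0.26, which is 29.2-fold lower (limma adjusted p = 3.96e-06). Of the 12 lowest, 3 were again collagens, the most that the rule allowed for this prefix. They were col-36 at -4.36 ± 0.32, col-158 at -3.56 ± 0.87 and col-2 at -3.44 ± 0.76. The fatty acid and retinol binding gene far-7 was at -3.94 ± 0.08, the acyl-CoA synthetase gene acs-2, known to be raised by fasting, at -3.89 ± 0.48, and the fatty acid desaturase gene fat-3 at -3.68 ± 0.44. The others were pals-39 at -3.80 ± 0.83, scl-2 at -3.73 ± 0.29, dod-3 at -3.73 ± 1.07, the alcohol dehydrogenase gene adh-1 at -3.71 ± 0.15 and the C-type lectin gene clec-60 at -3.60 ± 0.84. Of genes with only a sequence name, T16A9.5, F53B6.4 and T13F2.9 were highest at 3.54 ± 0.33, 3.47 ± 0.31 and 3.45 ± 0.66, and F45D3.4, F40G12.5 and F26A3.4 lowest at -3.83 ± 0.32, -3.48 ± 0.37 and -3.42 ± 0.18.

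**Figure D1:**
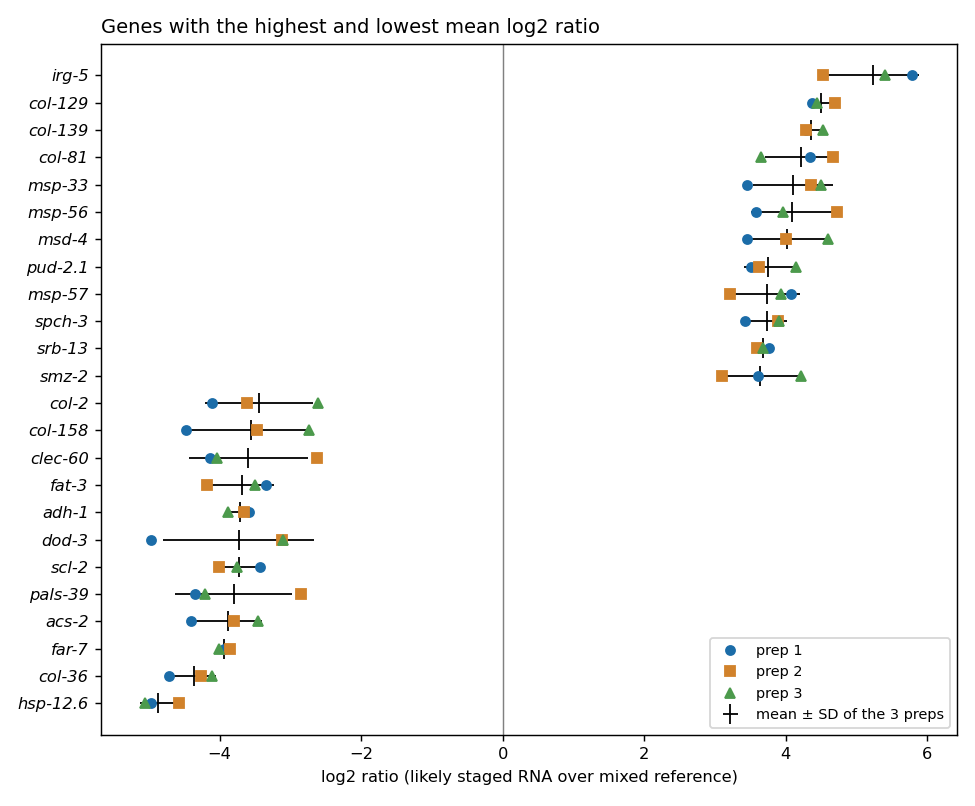
Log2 ratios (x axis) of the 12 highest and 12 lowest genes named by the fixed rule, 1 per row, with 1 point per prep and the mean ± SD. Every point of the upper 12 genes lies above 0 and every point of the lower 12 below 0, from irg-5 at a mean of 5.24 to hsp-12.6 at -4.87.

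In all, 3126 of the 15119 genes (20.7%) differed from the reference, 1709 higher and 1417 lower (limma, adjusted p under the threshold of 0.05). At least 2-fold differences were reached by 1283 of the higher and 910 of the lower genes. The sign was the same on all 3 arrays for 53.0% of genes. For independent arrays 25% would be so by chance, but these share the reference RNA and the channel of the staged RNA. Without prep 1, limma called 1763 genes, 1095 higher and 668 lower, of which 1679 were among the 3126, and the share of higher calls went from 54.7% to 62.1%.

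Nearly all major sperm protein genes were higher, and most other sperm genes. Of 30 major sperm protein genes, whose product is the cytoskeletal protein of nematode sperm, 29 were higher, 0 were lower and 1 did not pass, with the same count adjusted over the list alone. The lowest called member was msp-49 at 1.54 ± 0.88, and msp-38 at -0.19 ± 0.49 was the one that did not pass. The list's median was 2.86 ± 0.16, or 7.26-fold (camera adjusted p = 1.57e-30). With an estimated correlation, adjusted p = 0.376. Members of this family are near-identical and may share signal, so the 29 are not independent. Of 68 other sperm genes, 42 were higher, 2 lower and 24 did not pass, or 45 higher and 2 lower adjusted over the list alone, and their median was 1.29 ± 0.19 (camera adjusted p = 2.92e-20; adjusted p = 0.376 with an estimated correlation). The highest of these 68 were smz-2 and sss-2, the latter at 3.44 ± 0.19. The 2 that were lower were spe-27 at -0.87 ± 0.22 and swm-1, which encodes a protease inhibitor that keeps sperm from activating early in males, at -1.35 ± 0.30. The call of spe-27 was lost without prep 1 (-0.76) or prep 2 (-0.88).

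Some genes of germline stem cells and meiosis were higher. Of 48 measured, 16 were higher, 0 were lower and 32 did not pass; adjusted over the list alone, 21 were higher. The helicase genes glh-1 and glh-2, whose products lie in the P granules of germ cells, were highest at 2.44 ± 0.36 and 2.11 ± 0.36. The lowest members, him-5 at -0.34 ± 0.33 and mes-3 at -0.35 ± 0.09, did not pass. The list's median was 0.91 in prep 1, 0.47 in prep 2 and 0.43 in prep 3, a mean of 0.60 ± 0.27 (camera adjusted p = 6.46e-08; adjusted p = 0.441 with an estimated correlation).

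Genes of oocytes and of the cell cycle differed between the preps. The median of 40 oocyte and eggshell genes was 1.12 in prep 1, -0.06 in prep 2 and -0.09 in prep 3, a mean of 0.32 ± 0.69. Of these genes 4 were higher and 36 did not pass, and 1 was higher adjusted over the list alone. The egg activation gene egg-4 was at 1.37 ± 0.15 and the eggshell gene cbd-1 at 1.35 ± 1.26, while meg-4 at -0.36 ± 0.27 and skr-1 at -0.51 ± 0.37 did not pass. The list passed with camera (adjusted p = 0.0320), not with an estimated correlation (adjusted p = 0.772). Without prep 1 its median was -0.08 (adjusted p = 0.850), without prep 2 0.52 and without prep 3 0.53, and with print-block centring it was 0.24 (adjusted p = 0.118). The 51 cell cycle and DNA replication genes had medians of 0.99, 0.23 and 0.16 in preps 1, 2 and 3, a mean of 0.46 ± 0.46 (camera adjusted p = 2.70e-04; adjusted p = 0.552 with an estimated correlation). Without prep 1 this list stood at 0.20 (adjusted p = 0.0469). Of these 9 were higher, 7 adjusted over the list alone, led by the kinesin genes klp-7 at 1.74 ± 1.23 and klp-19 at 1.63 ± 0.37. The lowest were cdk-4 at -0.61 ± 0.51 and cdc-25.2 at -0.73 ± 0.33, and neither passed. The 3 yolk protein genes measured did not pass, with vit-2 at 0.54 ± 0.94, vit-6 at 0.16 ± 0.68 and vit-5 at -0.08 ± 0.43. The yolk list's median was 0.87 in prep 1, 0.15 in prep 2 and -0.54 in prep 3 (camera adjusted p = 0.643). Without prep 1, cbd-1 was at 0.74 and klp-7 at 1.13, and neither passed; without prep 3, vit-2 passed at 1.09.

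Cuticle collagens moved both ways. Of 152 measured, 69 were higher, 27 lower and 56 did not pass; adjusted over the list alone the counts were 74 and 32. Members ranged from col-129 and col-139, given above, to col-158 and col-36. The list's median was 0.10 in prep 1, 0.93 in prep 2 and 1.00 in prep 3, a mean of 0.68 ± 0.50 (camera adjusted p = 1.35e-05; adjusted p = 0.546 with an estimated correlation). The direction turned when a single gene stood for the whole col family, to a median of -0.29. Of 9 collagens known from the adult cuticle, 7 were higher and 0 lower over all genes, and 7 higher and 1 lower adjusted over the list alone. They were led by col-62 at 4.05 ± 0.75 and col-7 at 3.80 ± 0.39. In this list col-63 at 0.38 ± 0.61 and rol-6 at -1.45 ± 1.85 did not pass over all genes. Its median was 1.29, 1.94 and 3.30 in preps 1, 2 and 3, a mean of 2.18 ± 1.03 or 4.52-fold (camera adjusted p = 2.28e-06; adjusted p = 0.376 with an estimated correlation). Of 77 moulting genes, which include the hedgehog-related families, 4 were higher and 15 lower, also adjusted over the list alone. The lowest were wrt-10 at -2.63 ± 1.31 and grl-3 at -2.63 ± 0.66, both hedgehog-related, and grl-4 was higher at 1.18 ± 0.91. The protease gene nas-36, needed for moulting, was at 1.31 ± 1.72 and did not pass. The moulting list's median was -0.67, -0.16 and -0.02 in preps 1, 2 and 3, a mean of -0.28 ± 0.34 (camera adjusted p = 0.00742; adjusted p = 0.657 with an estimated correlation). Without prep 1 it was -0.09 (adjusted p = 0.647). Single calls also hung on the prep left out. While grl-4 did not pass without prep 2 (0.71), rol-6 passed without prep 2 (-1.83) or prep 3 (-2.12). The gene nas-36 passed without prep 1 (2.13) or prep 2 (1.39). The passes without prep 2 rest on arrays that disagree. In preps 1 and 3, nas-36 stood at -0.33 and 3.11, of opposite sign, and rol-6 at -3.56 and -0.11.

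Most neuropeptide genes were lower, as were some neuronal genes, and some muscle genes were higher. Of 100 neuropeptide and insulin-like genes, 58 were lower, 2 were higher and 40 did not pass, or 60 and 2 adjusted over the list alone. The median was -0.86 ± 0.15, 1.82-fold lower (camera adjusted p = 7.12e-16; adjusted p = 0.376 with an estimated correlation). The lowest were flp-1 at -2.90 ± 0.51 and nlp-17 at -2.34 ± 0.62, and the higher ones nlp-25 at 1.07 ± 0.59 and nlp-4 at 0.93 ± 0.41. Of 83 neuronal genes, 17 were lower, 0 were higher and 66 did not pass, with the same counts adjusted over the list alone. They included ida-1, a dense core vesicle gene, at -1.95 ± 0.60 and unc-13, needed for synaptic vesicle release, at -1.84 ± 0.49. The highest, mec-17 at 0.57 ± 0.14 and acr-18 at 0.56 ± 0.99, did not pass. The neuronal median was -0.53 ± 0.19 (camera adjusted p = 1.99e-06; adjusted p = 0.441 with an estimated correlation). Of 42 muscle genes, 14 were higher, 1 was lower and 27 did not pass, or 15 and 1 adjusted over the list alone, with a median of 0.49 ± 0.32 (camera adjusted p = 3.84e-05; adjusted p = 0.441 with an estimated correlation). The troponin T gene mup-2 was highest at 2.45 ± 0.03. Next came act-5 at 2.17 ± 0.24, which encodes an actin of the intestine rather than of muscle. The troponin C gene tnc-2 was lower at -1.18 ± 0.75, and dys-1 at -0.42 ± 0.73 did not pass. Of 29 vulva and uterus genes, only hlh-2 passed, at -1.56 ± 0.65, over all genes and adjusted over the list alone. In that list exc-6 at 0.26 ± 0.28, let-60 at 0.23 ± 0.18 and vab-23 at -0.74 ± 0.35 did not pass. Its median was -0.27 ± 0.08 (camera adjusted p = 0.0373; adjusted p = 0.441 with an estimated correlation), and without prep 3 the call was lost (adjusted p = 0.214). Of single genes, nlp-25 was no longer called without prep 2 (0.95) or prep 3 (0.87), nlp-4 without prep 1 (0.93) or prep 3 (0.72), and tnc-2 without prep 1 (-0.91) or prep 2 (-1.02).

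Some genes of protein synthesis and respiration were higher. Of 63 ribosomal protein genes, 20 were higher, 0 were lower and 43 did not pass, or 30 and 0 adjusted over the list alone. The list stood at a median of 0.67 ± 0.27 (camera adjusted p = 1.46e-10; adjusted p = 0.441 with an estimated correlation). The highest were rpl-15 at 1.77 ± 1.06 and rpl-11.1, which was 2.82-fold higher with an SD of 0.45 on the log2 scale, and the lowest, rpl-23A.1 at -0.04 ± 0.43 and rpl-29 at -0.05 ± 0.27, did not pass. Of 36 genes of mitochondrial respiration, 10 were higher, 0 were lower and 26 did not pass, or 13 and 0 adjusted over the list alone, with a median of 0.51 ± 0.17 (camera adjusted p = 1.74e-05; adjusted p = 0.441 with an estimated correlation). The complex I genes nuo-5 and nuo-1 stood at 1.44 ± 0.29 and 1.29 ± 1.18, and cox-6A at -0.17 ± 0.14 and cox-11 at -0.29 ± 0.39 did not pass. The call of nuo-1 was lost without prep 1 (1.64) or prep 2 (0.61).

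Few early embryonic zygotic genes passed the test. Of 62 measured, 6 were lower, 1 was higher and 55 did not pass, or 5 and 1 adjusted over the list alone. The homeobox gene ceh-32 at -1.70 ± 0.63 and sdz-24 at -1.56 ± 0.47 were lowest, sdz-3 was higher at 1.24 ± 1.00, and the endoderm gene end-1 at 0.49 ± 0.29 did not pass. Without prep 2, sdz-3 was at 0.70 and did not pass. The list's median was -0.32 ± 0.04 (camera adjusted p = 0.00149; adjusted p = 0.376 with an estimated correlation).

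The remaining lists did not pass as a whole. The 356 genes of intestinal families had a median of 0.01 ± 0.06 (camera adjusted p = 0.348), yet 60 were higher and 33 lower, or 61 and 34 adjusted over the list alone. They ran from dod-19 at 3.46 ± 0.34 and the glucuronosyltransferase gene ugt-22 at 3.23 ± 0.19 to clec-60 and dod-3. With 1 gene standing for each family the median was 0.28, not tested. The 149 heat shock and stress genes had a median of -0.02 ± 0.11 (camera adjusted p = 0.941), with 19 higher and 16 lower, or 20 and 17 adjusted over the list alone. The cytochrome P450 genes cyp-35A3 at 2.25 ± 0.44 and cyp-35C1 at 2.01 ± 0.59 were highest, and the small heat shock gene hsp-12.3 at -2.86 ± 0.33 and hsp-12.6 lowest. The 62 histone genes had a median of -0.03 ± 0.22 (camera adjusted p = 0.643), with 3 higher and 5 lower, also adjusted over the list alone. Linker histone genes stood at both ends, with hil-4 at 1.61 ± 0.42 against hil-3 at -2.71 ± 0.68 and his-24 at -2.14 ± 0.12, and his-70 was higher at 1.15 ± 0.17. The 14 heterochronic genes had a median of -0.19 ± 0.38 (camera adjusted p = 0.427), with hbl-1 at -0.97 ± 0.45 and ain-1 at -0.77 ± 0.28 lower; 1 of these passed adjusted over the list alone. In that list mab-10 at 0.64 ± 0.14 and lin-41 at 0.50 ± 0.48 did not pass. The call of ain-1 was lost without prep 1 (-0.69), 2 (-0.93) or 3 (-0.68), and that of hbl-1 without prep 1 (-0.76). Of 18 male-specific genes, 0 passed limma's test over all genes or adjusted over the list alone, and the median was -0.12 ± 0.06 (camera adjusted p = 0.393). Among them dmd-5 stood at 0.38 ± 0.35, lov-1 at 0.24 ± 0.25, klp-6 at -0.43 ± 0.26 and dmd-4 at -0.66 ± 0.93; without prep 2, dmd-4 passed at -1.07. Of the 21 lists, 15 passed with camera's preset correlation, 10 higher and 5 lower, and 0 passed with a correlation estimated from the 3 arrays (lowest adjusted p = 0.376).

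**Figure D2:**
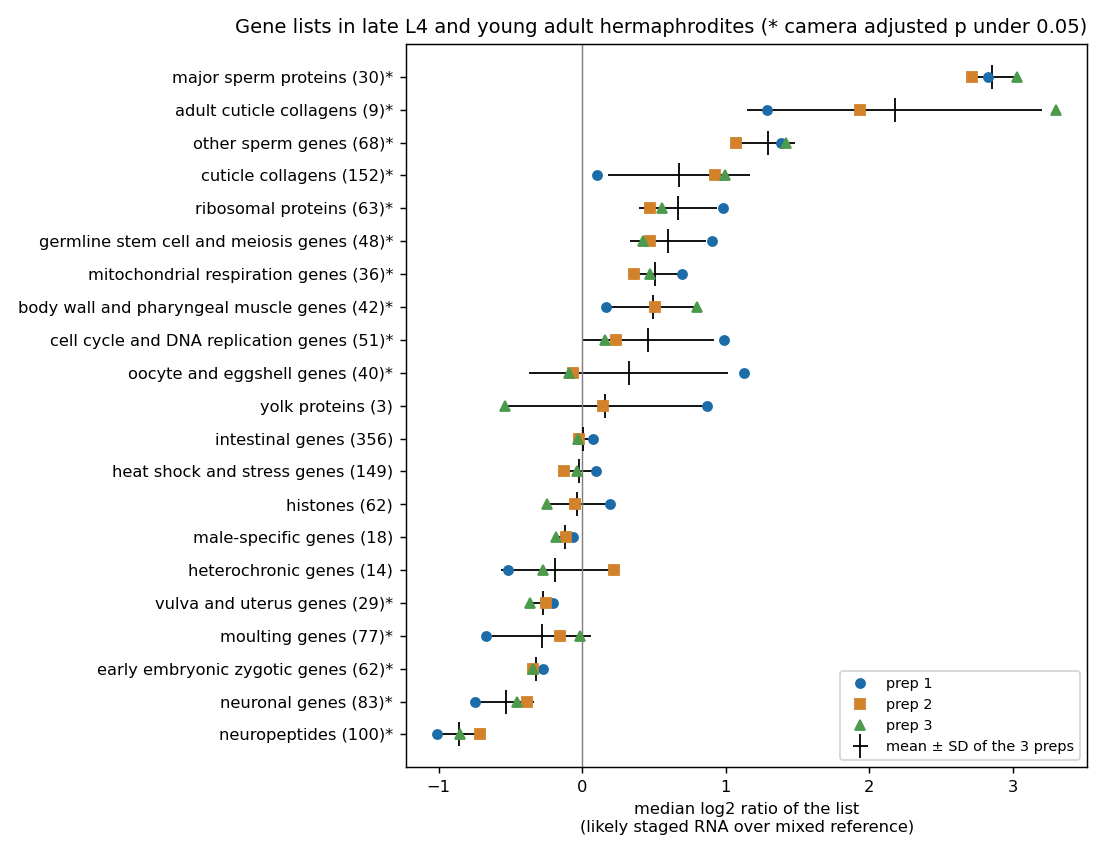
Median log2 ratio (x axis) of each fixed gene list (rows, with the number of measured genes), 1 point per prep, with the mean ± SD of the 3 preps; asterisks mark a camera adjusted p under 0.05 at the preset correlation. Major sperm proteins lie at 2.72 to 3.03 in all preps, and the oocyte list at 1.12 in prep 1 against -0.06 and -0.09 in the other preps.

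X-linked genes were compared with autosomal genes because genes active in the germ line are known to be rare on the X chromosome. The 2258 X-linked genes had a median of -0.27 and the 12789 autosomal genes of 0.01. The difference was -0.32, -0.11 and -0.41 in preps 1, 2 and 3, a mean of -0.28 ± 0.16 (camera p = 8.48e-06; p = 0.259 with an estimated correlation). Of X-linked genes 4.83% were called higher and 12.7% lower, against 12.5% and 8.80% of autosomal genes. By chromosome, the median was 0.15 ± 0.12 on III, 0.09 ± 0.08 on IV, 0.05 ± 0.13 on I, 0.04 ± 0.15 on II and -0.14 ± 0.11 on V. Position on the array and chromosome were partly confounded, since 2255 of the X-linked genes lay in the last 16 print blocks. Within these blocks the difference from the 5196 autosomal genes there was -0.18 ± 0.07 (camera p = 0.00234; p = 0.396 with an estimated correlation). Most of these autosomal genes, 3879, were on chromosome V, and against them the difference was -0.13 ± 0.07 (camera p = 0.0229; p = 0.506 with an estimated correlation). Against the 1300 genes of chromosome IV in the same blocks it was -0.34 ± 0.05 (camera p = 3.69e-08; p = 0.186 with an estimated correlation). X-linked genes lay below the autosomal genes of the same print block in 15 of 16 blocks, by a mean of -0.15 ± 0.11 (SD over blocks). With each array centred within print blocks the difference was -0.15.

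**Figure D3:**
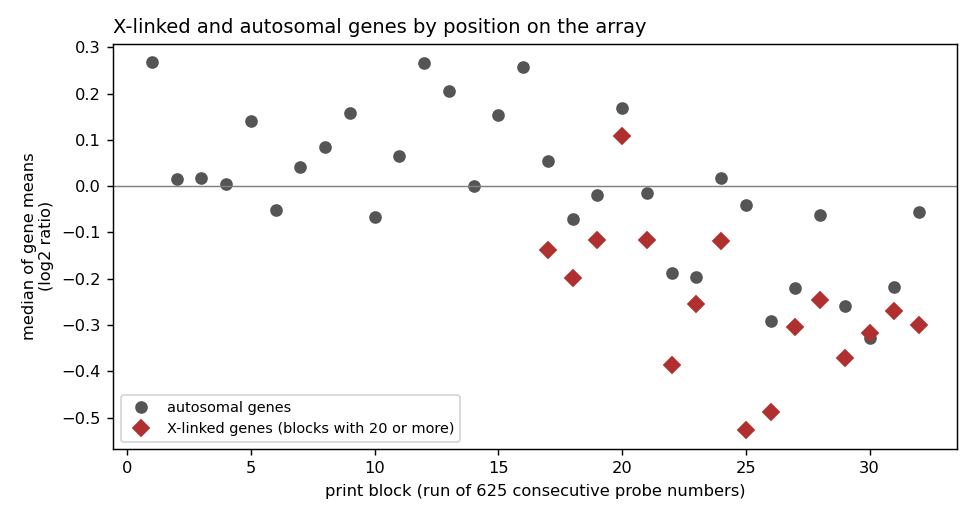
Median of the genes' mean log2 ratios (y axis) in each print block (x axis), for autosomal genes (circles) and X-linked genes (diamonds, blocks with 20 or more). Diamonds lie below circles in 15 of the 16 blocks that hold both.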

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

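No paired analysis was possible because there is 1 group. The test on print-block centring and that on the last 16 print blocks were chosen after the data were seen. The filter on dim spots was not run because the files give no intensities. The total of 3126 genes stayed between 2827 and 3296 under other centring, scaling, weights, missing-value and spot rules, and was 3042 with print-block centring, where 2601 of the called genes were shared. The share of higher calls, 54.7%, ranged from 54.2% to 63.2% over the alternatives, highest with treat, and would become the share of lower calls if the ratio ran the other way. An adjusted p under 0.01 left 1605 genes, 952 higher and 653 lower, and limma's treat against 1.5-fold left 964, 609 higher and 355 lower; a minimum of 2-fold left 910 lower genes. Leaving out 1 prep gave 1763 to 2901 genes, 1095 to 1598 higher and 668 to 1303 lower, with prep 1 left out at the low end. Leaving out 1 prep kept 13 to 15 lists past the threshold. Their medians spanned -0.08 to 0.53 for the oocyte list, whose sign turned without prep 1, 0.20 to 0.61 for cell cycle genes, -0.41 to -0.09 for moulting genes and -0.31 to -0.23 for vulva and uterus genes. Array weights (0.20, adjusted p = 0.148) and print-block centring (0.24, adjusted p = 0.118) also ended the oocyte call. An estimated correlation left 0 lists. It does not change the medians, which were 2.86, 1.29, 0.32, 0.60, 0.46, -0.32, 0.68, 2.18, -0.28, -0.27, 0.49, -0.53, -0.86, 0.67 and 0.51 in the order of the lists from major sperm proteins to mitochondrial respiration genes, nor the X difference of -0.28, which also lost its call. With 1 gene per family, the member of middle rank by mean log2 ratio, the list medians were as follows. They were 2.68 for major sperm proteins, 1.55 for other sperm genes, -0.37 for embryonic genes and 0.28 for intestinal genes. The major sperm protein list is a single family, so 2.68 is its middle member and was bound to lie near the list's median. That value cannot tell whether the shift outlasts the removal of near-identical members. For cuticle collagens the rule of 1 gene per family leaves the dpy, sqt, rol, bli and lon genes and a single col gene. It gave -0.29, so the list's positive median rests on the col genes. The X difference was -0.37 to -0.22 with 1 prep left out and -0.27 without the sperm, oocyte and germline lists, which hold too few genes to move it much. Of 1133 values of the 103 named genes under alternatives, 1097 kept their call, 27 lost it, 9 gained it and 0 reversed. Among the 1097 were 8 values of uncalled genes whose sign turned. Without prep 1 the median was -0.078 (adjusted p = 0.850) for oocyte genes and -0.086 (adjusted p = 0.647) for moulting genes. The causes of the other changes were not tested. Signal over background is unknown, which limits what can be said of genes near 0.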

Other observations

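Of the families, tests and singly named genes outside the naming rule below, all were chosen after the gene values were seen, except that the predictions on germline lists, nuclear pore genes, DAF-16 target genes, heat-inducible genes and print-block centring of the oocyte list were written before those values were computed. Predictions on the correlation of close probe numbers were also tested, and were taken out of the patterns weighed below after their results were seen. In that test, deviations of spots 25 numbers apart correlated by 0.21 to 0.30, and those of neighbouring genes on a chromosome that lie far apart on the array by 0.11, 0.13 and 0.14 in preps 1, 2 and 3. Gene families outside the fixed lists, taken by symbol prefix with at least 8 members, also shifted. Of 147 families 23 passed camera's test after adjustment, 11 higher and 12 lower, and 0 passed with an estimated correlation (lowest adjusted p = 0.713). The abu family stood at a median of 0.77 in prep 1, 2.12 in prep 2 and 2.12 in prep 3, with 9 of 13 members higher. The vha family, subunits of the vacuolar proton pump, stood at 0.82 ± 0.12 with 8 of 16 higher, the rpn family, subunits of the proteasome, at 0.83 ± 0.33 with 7 of 13 higher, and the ttbk family of kinases at 1.57 ± 0.61 with 7 of 9 higher and 1 lower. Among those that were lower, the pals family stood at -0.64 ± 0.19 with 8 of 24 lower and the neuropeptide receptor family npr at -0.46 ± 0.10 with 5 of 41 lower. The nuclear receptor family nhr stood at -0.28 ± 0.04 with 39 of 232 lower and 1 higher. Adjusted over the family alone, 10 pals, 1 npr and 31 nhr genes were lower.

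Spots with no listed gene carried signal too. Of 4004 such spots with a value on all arrays, limma called 409 (10.2%), adjusted over these spots alone, against 20.7% of the genes tested. Of the called spots 244 were higher and 165 lower, and the means of the 4004 spots reached 4.94 and -3.46. On the last 16 print blocks, genes of chromosome V lay below those of chromosome IV by -0.21 ± 0.03 (camera p = 0.00131; p = 0.174 with an estimated correlation).

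Differences between print blocks do not account for all of the lower values of X-linked genes, since within print blocks the difference was -0.15. Its standard error over 16 blocks was 0.028, but the blocks share the same 3 arrays and are not independent replicates. Their borders were inferred, and an effect of position within blocks was not tested, so position is not excluded. The difference within blocks is smaller than the pooled -0.28, and the autosomal genes compared were not the same. Their median was 0.01 over all blocks and -0.09 in the last 16 blocks. Chromosome V genes, themselves low, make up most of the autosomal genes in these blocks. Chromosome IV genes had a median of 0.06 in these blocks, against 0.09 for all chromosome IV genes. How much of the gap the make-up by chromosome accounts for was not tested. A shortage of germline genes on the X chromosome stays open as a candidate explanation: 2.54% of the 236 genes in the sperm, oocyte, germline and cell cycle lists were X-linked, against 15.2% of the other 14811 (two-sided Fisher's exact p = 2.72e-10). That share restates what is known of these genes' chromosomes and uses no expression value. Leaving the lists out gave -0.27, but they hold too few genes to decide how much of the difference the shortage makes up.

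The oocyte list differed between the preps more than random lists did. Its SD over the 3 arrays was 0.69 as deposited and 0.67 after print-block centring. The 95th percentile was 0.15 for 1000 random lists of its size after the same centring. The list was weighed because its spread had been seen, and its genes correlate (estimated correlation 0.55), so exceeding random lists is no independent test. As centring left the SD nearly unchanged, differences between the inferred print blocks do not account for the spread. An effect of position within blocks was not tested, so position is not excluded. The preps may have differed slightly in age: the 21 nuclear pore genes, in no fixed list, had a median of 0.84 in prep 1, which is 0.43 above the higher of the other preps, more than in 98.5% of random lists. The excess was not particular to these genes: ribosomal proteins stood at 0.98, 0.47 and 0.56 in preps 1, 2 and 3, and the rsp family at 0.92, 0.13 and 0.33. Each prep had its own array, whose title carries its own date, so a difference in age cannot be separated from other differences of the RNA or of the array and day, and stays open.

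Several of the lowest genes, such as hsp-12.6, acs-2 and dod-3, are known to rise in fasting, dauer or long-lived animals, and a hypothesis is that the mixed reference held more of such animals than the staged RNA. Of 14 other genes known to be raised by the transcription factor DAF-16, 4 were lower, among them ftn-1 at -2.50 ± 0.36, and 1, lys-8, was higher at 1.23 ± 0.43. Their median was -0.30 ± 0.21 (camera p = 0.0232, adjusted p = 0.0695 over the 3 lists tested, 0.412 with an estimated correlation), so the shift met the prediction before adjustment and failed after it. A heat shock of only 1 of the RNAs is weakly argued against by the mean of 5 hsp-16 and hsp-70 genes. A shock common to both RNAs would not show in the ratio, and whether these spots exceeded background is unknown. The mean of these 5 genes was -0.28 ± 0.14 and stayed between -0.42 and -0.15 on the 3 arrays, although hsp-70 alone was lower at -1.05 ± 1.00. The median of these genes was less steady, at 0.18, -0.54 and -0.34 in preps 1, 2 and 3. The hypothesis on the mixed reference stays open, as a set of 13 genes known to be lowered by DAF-16 did not move the other way. This set was a selection. It held several dod genes but not dod-19, which stood at 3.46 ± 0.34. Of the 13 genes in the set, 2 were higher and 2 lower. Their median was 0.09, 0.12 and -0.53 in preps 1, 2 and 3, a mean of -0.11 ± 0.36 (camera adjusted p = 0.857).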
